A study of Mus musculus with 11 samples.

How the data were processed

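Contact maps were made by Hi-C on mouse Th1 cells, per the labels: 10 single cells, of which 9 were cut with Bgl II and 1 with Dpn II, and 1 population (ensemble) map cut with Bgl II. A pooled single-cell map came with the series. Single-cell libraries were made by binding biotin-labelled junctions to streptavidin beads and cutting with Alu I before PCR, per the labels' protocols. The genome build was mm9, per the submitters' processing notes. The aligner and the filters on read pairs are not given in the sources used here.

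The deposited files hold genomic positions in bp, 1 line for each contact, with a chromosome and a coordinate for both fragment ends, per the file headers. They hold distinct contacts with no read number: no pair of ends was listed more than once in any of the 12 files. Repeated ligations of 1 pair of ends, in many cells of the ensemble, therefore count once. Coordinates of the Bgl II cells lay 2 to 4 bp below the ensemble's for 98.1% to 98.5% of ends, a shift far smaller than any bin used. In cell 8, 3 contacts with a mitochondrial end were left out. In the ensemble, 2580 contacts with both ends at 1 position were kept. Chromosomes 1 to 19 and X were used.

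All computation was in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The decay slope was a least squares fit on log scales to autosomal cis contacts in log-spaced distance bins, divided by the possible positions. Domains were called on the ensemble from minima of insulation (50 kb bins, 500 kb window, prominence 0.1) after 50 iterations of balancing, leaving out bins under 0.2 of the median row sum. Compartment classes were the sign of the first eigenvector of the ensemble's cis correlation matrix per chromosome, at 1 Mb. The design called for the sign to be set by gene annotation. With no mm9 annotation used here, it was set by the density of ensemble fragment ends, a choice made after the data were examined, so the classes are numbered. With this sign 0 of 190 chromosome pairs were opposite in ensemble trans contacts, and 20 of 20 chromosomes had more Dpn II ends of cell 8 per Bgl II end in class 1. The gene groups fixed beforehand, and the genes named beforehand, were not analysed here for the same reason.

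Tests ran within each map, with 1000 draws for the main settings and 200 for the alternatives, and Benjamini-Hochberg adjustment over the 10 cells at a threshold of 0.05. Domain boundaries and class tracks were shifted circularly along each chromosome. Trans counts over 190 chromosome pairs were set against multinomial draws with the ensemble's shares. Long-range contacts were set against contacts drawn from the ensemble, matched on chromosome and distance class in cis. A neighbour lay within 1 Mb at both ends and shared no fragment end, except in the sharing comparison, where a shared fragment end was allowed. X and autosomes were compared within each cell by Fisher's exact test on fragment ends. These draws treat contacts of 1 map as the units, so a p says that 1 map differs from its null, not that cells or groups differ. Means and SDs are over the 9 Bgl II cells. Shares have 95% Wilson intervals, and where a count was 0 the limit given is 3 counts of the total.

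The tests were checked on simulated maps, 20 without and 20 with a planted effect. Without an effect, calls were made in 0 maps for chromosome pairs, 2 for clustering, 2 for trans classes, 1 for domains and 1 for the trans share by class. With one, 20 of 20 were called in each of the first 4, and 8 of 20 for the trans share by class. Maps without an effect held contacts drawn independently, so these rates do not cover the grouped contacts of real cells. Each effect was planted at a single size, and smaller effects were not checked. Clustering was simulated for cis contacts alone and pairing within classes for trans contacts alone. The sharing test and the X comparison were not simulated.

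The rule for named regions was fixed before the data were examined: in each cell the chromosome pair with the largest excess of trans contacts; of domains with at least 100 contact ends in the 10 cells summed, the 5 highest and 5 lowest trans shares; the 5 domain pairs over 5 Mb apart with the most contacts in 1 cell; and the 5 regions of 500 kb with the fewest ensemble contact ends per fragment end relative to their chromosome. A minimum of 20 fragment ends per region was added to the last. Alternatives tried were other distance ranges, bin sizes and windows, no balancing, other nulls, no X, other radii, all 10 cells, each cell left out, and cells thinned to 11156 contacts.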

Results

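Hi-C joins DNA ends that lie close together in the nucleus and reads the joined pairs, so that each contact is a pair of restriction fragment ends. Contact maps of mouse Th1 cells were compared here: 10 maps of single cells, 1 single-cell map pooled by the authors, and 1 ensemble map of a cell population. Th1 cells are CD4-positive helper T cells, grown here from spleens of male C57BL/6 mice. Chromatin of 9 cells, and of the ensemble, was cut with Bgl II, and that of cell 8 with Dpn II, an enzyme with a shorter recognition site. The 9 Bgl II cells held between 11156 and 30665 contacts (mean 19447.2 ± 6912.9, SD, n = 9), cell 8 held 12225, the pool 2294791 and the ensemble 51834382. Every contact of the 9 Bgl II cells was also in the pool, where they made up 7.62% of the contacts, and 92.4% of the pool was in none of them. The Bgl II cells shared almost no identical contact, with 0 to 6 per pair of cells over 36 pairs. No label names separate animals or cultures, so the cells cannot be taken as separate biological replicates. SDs and p-values describe these cells alone, the spread between them may be technical, and groups of maps were not tested against each other. Wilson intervals cover counting error alone.

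The design asks how much chromosome structure differs from cell to cell. Contacts between chromosomes (trans contacts) made up 17.9% ± 6.71 (SD, n = 9) of all contacts in the Bgl II cells, and their share varied between cells far beyond counting error. Cell 1 had the lowest share, 6.96% (95% Wilson interval 6.68 to 7.25), and cell 2 the highest, 25.9% (25.4 to 26.4). Cells 6 and 7 held 10.6% and 14.2%, and cells 3 and 4 25.03% and 25.05%. The pool held 20.2% and the ensemble 50.7%, above each of the 10 cells.

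**Figure D1:**
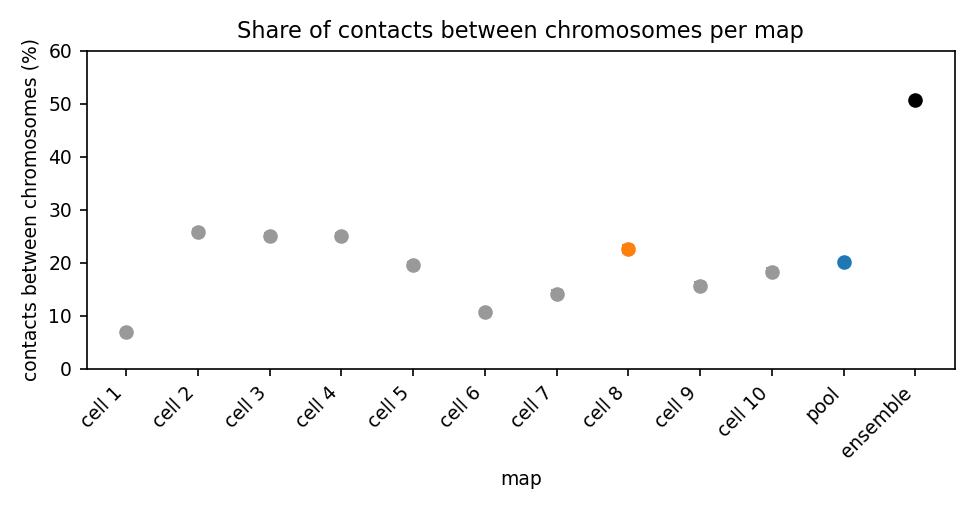
Share of contacts between chromosomes (%, vertical axis) in each map (horizontal axis), with 95% Wilson intervals, most of them smaller than the points; grey points are Bgl II cells, orange is the Dpn II cell, blue the pool and black the ensemble. The cells lie between 6.96% and 25.9%, and the ensemble at 50.7%.

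Within chromosomes, contact density fell with distance in all maps, except between 10.0 and 15.9 Mb in cell 1, where it rose. The slope on log scales between 100 kb and 10 Mb was -0.986 ± 0.0902 (SD, n = 9) in the Bgl II cells, -1.02 in the pool and -0.904 in the ensemble. Cell 4 had the shallowest slope, -0.807, with 46.7% (45.9 to 47.5) of its autosomal cis contacts over 10 Mb, and cell 10 the steepest, -1.14, with 24.7% (23.8 to 25.6). Cell 1 had many cis contacts over 10 Mb, 40.05%, but few over 50 Mb, 4.15% (3.92 to 4.39), against 15.4% (14.8 to 16.0) in cell 4 and 12.1% in the ensemble. Fitted from 500 kb to 50 Mb the mean slope was -0.649.

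**Figure D2:**
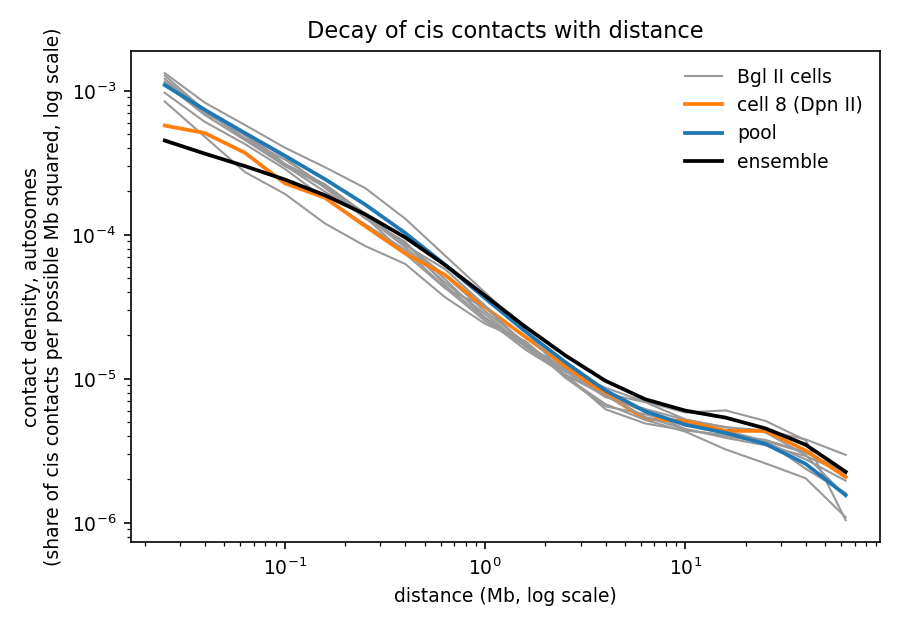
Density of autosomal cis contacts (share of a map's cis contacts per possible squared Mb, log axis) against distance (Mb, log axis), with 1 line per map, grey for Bgl II cells, orange for the Dpn II cell, blue for the pool and black for the ensemble. The Bgl II slopes between 100 kb and 10 Mb lie between -1.14 and -0.807.

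The X chromosome, present in 1 copy in male cells, held fewer contact ends per Mb than the autosomes in every map. Its density was 0.327 ± 0.0210 (SD, n = 9) of the median autosome in the Bgl II cells, 0.320 in cell 8, 0.331 in the pool and 0.249 in the ensemble. Fragment ends with more than 1 partner were rarer on X than on autosomes in each of the 9 Bgl II cells, and 8 of them passed the test below. In cell 1 they were 1 of 1310 X ends against 1.82% of autosomal ends, and in cell 3 0 of 1013, which allows a share of up to 0.296%, against 1.90%. The adjusted p from Fisher's exact test (two-sided, Benjamini-Hochberg over 10 cells) was 2.21e-08 in cell 1 and 4.86e-08 in cell 3, the smallest among the 8 cells past the threshold of 0.05. Cell 10 (0.734% on X against 1.36%; adjusted p = 0.288, Fisher's exact test) and cell 8 (0 of 513 X ends against 0.230%; adjusted p = 0.633) did not pass, and with each cell thinned to the contact number of the shallowest cell 0 of 9 passed.

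The next comparison asks whether domains of the population map are seen in single cells. The ensemble was divided into 3647 domains with a median length of 650 kb, and in each single cell, contacts kept inside these domains more often than chance placement gives. Of cis contacts between 50 kb and 1 Mb, 69.8% ± 1.57 (SD, n = 9) lay inside 1 domain in the Bgl II cells, 7.04 points ± 0.647 (SD, n = 9) above boundaries shifted along each chromosome. The excess was 6.18 points in cell 1 and 8.15 in cell 3, the extremes of the Bgl II cells, 6.30 in cell 8, 7.09 in the pool and 7.80 in the ensemble, on which the domains were called. All 10 cells passed (permutation test, one-sided, adjusted p = 0.001 in each cell, the smallest that 1000 draws can give).

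At a larger scale, 2516 bins of 1 Mb were split by the first eigenvector of the ensemble's cis contacts into class 1, with more Bgl II fragment ends per Mb (39.1% of bins), and class 2. Both classes were seen in contacts between chromosomes in every cell. Trans contacts joined bins of 1 class more often than shifted tracks did, by 12.4 points ± 3.75 (SD, n = 9), from 5.13 points in cell 4 to 17.3 in cell 7, with 11.2 in cell 8, 12.4 in the pool and 4.16 in the ensemble. In cell 7, for example, 69.8% (67.7 to 71.8) of trans contacts joined bins of 1 class, against 52.5% with shifted tracks. Cis contacts over 10 Mb showed the same in each cell, with an excess of 16.4 points ± 3.20 (SD, n = 9), lowest in cells 1 (10.9) and 4 (11.4), 14.5 in cell 8, 17.5 in the pool and 10.8 in the ensemble. All 10 cells passed for trans and for cis contacts (permutation tests, one-sided, adjusted p = 0.001 in each cell, the smallest they can give). With classes called without balancing the ensemble matrix, the trans excess fell to 1.00 points and 1 of 9 Bgl II cells passed.

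**Figure D3:**
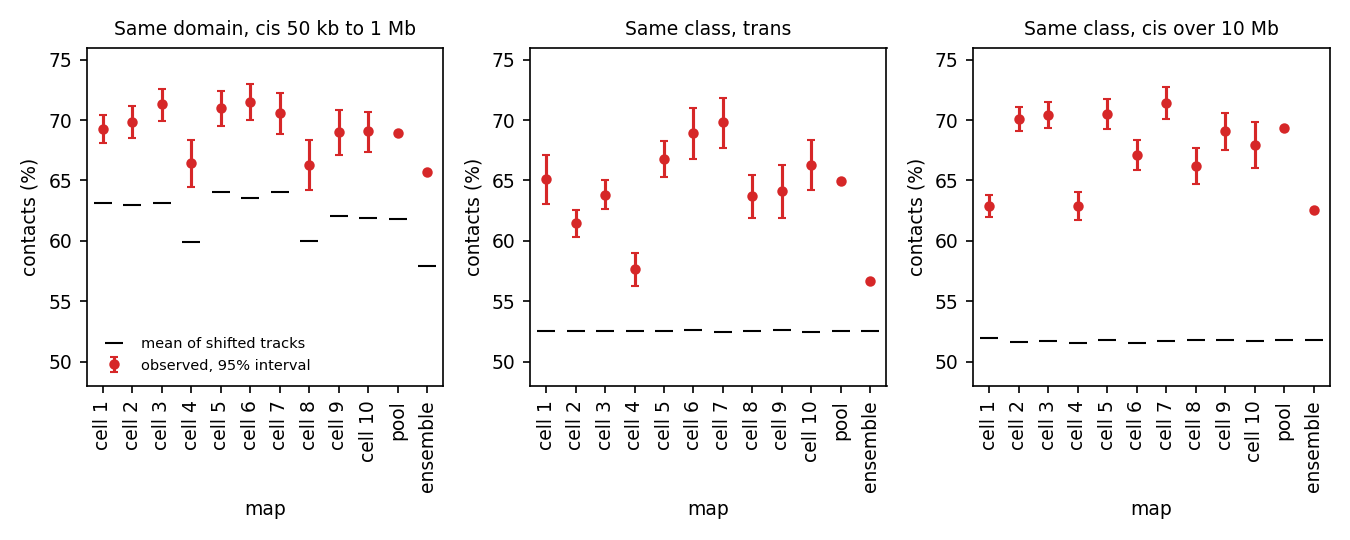
Observed shares (red points, %, with 95% Wilson intervals) and means of 1000 shifted tracks (black dashes) per map, for contacts inside 1 ensemble domain (left), trans contacts within 1 class (middle) and cis contacts over 10 Mb within 1 class (right). In each cell the observed share lies above the shifted tracks, least in cell 4 for trans contacts (5.13 points).

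With this sign, class 1 bins took a larger share of their contacts from other chromosomes than class 2 bins in every cell. The difference was 4.67 points ± 1.61 (SD, n = 9), from 2.90 in cell 5 to 8.61 in cell 4, where 29.96% of class 1 ends and 21.4% of class 2 ends were in trans contacts. It was 5.73 points in cell 8, 5.48 in the pool and 1.56 in the ensemble. All 10 cells passed (permutation test, two-sided, adjusted p = 0.002 in each cell, the smallest that 1000 draws can give).

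Of 1658 domains with at least 100 contact ends in the 10 cells summed, the median trans share was 20.7% in 768 class 1 domains and 15.6% in 876 class 2 domains. The highest share was on chromosome 17 from 35500001 to 36400000, a class 1 domain where 49 of 110 ends were in trans contacts (44.5%, 95% Wilson interval 35.6 to 53.9). It was above the cell's own mean in 10 of 10 cells, and 36.5% in the pool without the 9 Bgl II cells. Next came chromosome 11 from 114900001 to 115750000 (40.4%), chromosome 14 from 122600001 to 123450000 (37.3%, class 2), chromosome 11 from 3900001 to 5000000 (36.9%) and chromosome 5 from 137450001 to 138500000 (36.4%), with 28.4%, 25.5%, 28.7% and 28.0% in the pool without those cells. These were above the cell's own mean in 10, 10, 10 and 9 of 10 cells, and 1 cell gave up to 33.9% of the trans ends of a domain. The class of the chromosome 14 domain is weakly set, with an eigenvector value of -0.0375, near the border between classes. The lowest trans share was in a class 2 domain on chromosome 1 from 77300001 to 77950000, with 5 of 103 ends (4.85%, 2.09 to 10.9) and 11.6% in that pool. The chromosome 1 domains from 68450001 to 69250000 (5.36%) and from 101450001 to 102100000 (5.71%), both class 2, had 12.0% each in that pool. A class 1 domain on chromosome 9 from 69350001 to 69850000 (5.41%) and a class 2 domain on chromosome 15 from 51500001 to 52300000 (5.96%) had 19.1% and 19.2% there, where the whole pool had 20.2%. The chromosome 9 domain was above the cell's own mean in 3 of 10 cells, and of the 5 trans ends of the lowest domain 60% came from 1 cell. As the domains were picked for extreme values, the pool without the 9 cells is the less selected measure. Coordinates are on mm9, and no gene was assigned to a region, because no mm9 annotation was used here.

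In each cell, trans contacts gathered on some of the 190 chromosome pairs. Chromosomes 12 and 13 led in cell 2, with 191 contacts against 30.8 expected from the ensemble, chromosomes 15 and 19 in cell 1 (61 against 7.16) and chromosomes 1 and 3 in cell 4 (156 against 39.3). Chromosomes 2 and 10 led in cell 3 (145 against 47.1), 6 and 9 in cell 5 (142 against 24.7), 2 and 16 in cell 6 (58 against 10.7) and 2 and 9 in cell 7 (58 against 17.2). In cells 8, 9 and 10 the leading pairs were chromosomes 11 and 18 (106 against 14), 3 and 18 (29 against 7.11) and 13 and 17 (35 against 8.30). Chromosomes 2 and 16 were also at rank 3 in cell 1 (62 against 12.7), and 4 and 5 at rank 2 in cells 3 and 8 (129 against 49.6 and 90 against 22.5). Cell 1 had at least 1 contact on 144 pairs, cell 6 on 151 and cell 7 on 171, where draws with the ensemble's shares gave 189.6, 189.2 and 189.4 on average. The dispersion over pairs (1 under the ensemble's shares) was 16.7 ± 11.1 (SD, n = 9), from 4.42 in cell 9 to 36.9 in cell 4, and 15.9 in cell 8. All 10 cells passed (one-sided permutation test with multinomial draws, adjusted p = 0.001 in each cell, the smallest they can give). Dispersion grows with contact number, and with cells thinned to the shallowest its mean was 9.51. The draws take contacts as independent. With contacts within 1 Mb of each other at both ends counted once, the mean was 12.7, and 9 of 9 Bgl II cells passed.

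Contacts far apart on the genome came in groups within a cell. Of cis contacts over 5 Mb, 65.1% (64.3 to 65.9) in cell 1 and 19.2% (18.0 to 20.4) in cell 9, the extremes, had another contact of the cell within 1 Mb of both ends, against 48.6% and 16.4% in contacts drawn from the ensemble. The mean excess was 14.4 points ± 7.06 (SD, n = 9), and 17.7 in cell 8. Trans contacts were also grouped, with 37.8% in cell 1 and 5.84% in cell 9 against 0.519% and 0.434% in draws, a mean excess of 19.97 points ± 9.15 (SD, n = 9), and 15.6 in cell 8. All 10 cells passed for both kinds (one-sided permutation test by draws, adjusted p = 0.001 in each cell, the smallest they can give). The mean excess was 12.6 points for trans contacts of cells thinned to the shallowest, and 8.37 points for cis contacts at a radius of 2 Mb, with 9 of 9 Bgl II cells past the threshold in each. The domain pair over 5 Mb apart with the most contacts in 1 cell was on chromosome 6 in cell 1, from 31600001 to 32800000 and from 53700001 to 54500000, with 9 contacts against 0.328 expected from the ensemble and 1 contact in the other 9 cells. Domains on chromosome 1 from 172750001 to 174450000 and from 192700001 to 194000000 had 8 contacts in cell 3 against 1.21 expected, and the second of these had 8 with the domain from 162100001 to 163950000 in cell 1 against 0.844. In cell 1, 7 contacts joined chromosome 2 from 137800001 to 138750000 with 160900001 to 162700000 (0.403 expected), and 7 joined chromosome 4 from 118900001 to 120900000 with 125700001 to 127000000 (1.69 expected). In all, 3 domain pairs had 7 contacts, of which these are the first in order of cell. As the pairs were picked for high counts, the expected values are no test.

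**Figure D4:**
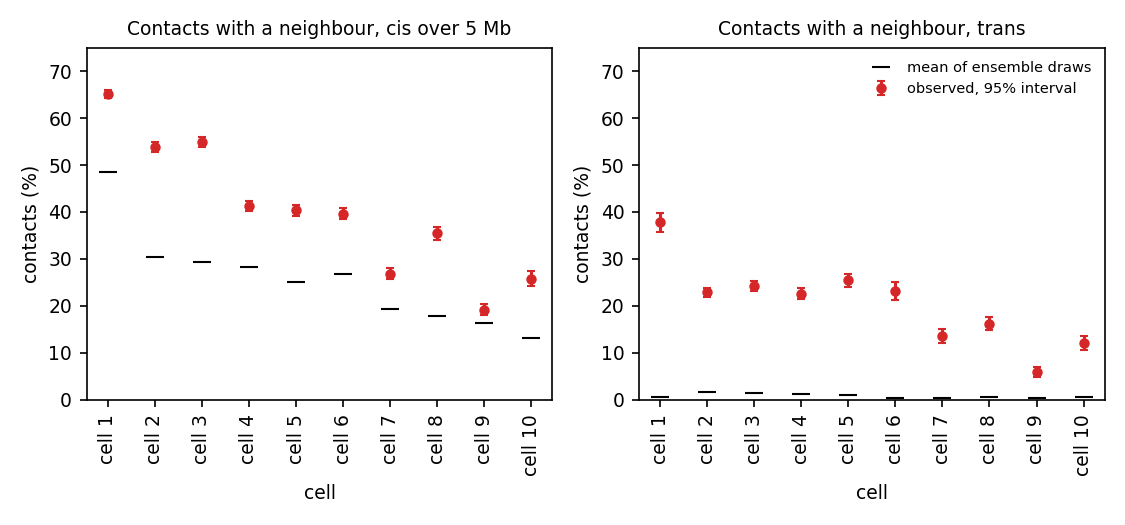
Contacts with another contact of the cell within 1 Mb of both ends (red points, %, with 95% Wilson intervals) and mean of 1000 draws from the ensemble (black dashes) per cell, for cis contacts over 5 Mb (left) and trans contacts (right). Observed shares lie above the draws in each cell, up to 65.1% in cis and 37.8% in trans, both in cell 1.

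Between cells, long-range cis contacts were shared little more or less than by the ensemble. At 2754 contacts searched per cell, 13.7% (cell 9) to 26.8% (cell 3) of a cell's contacts over 5 Mb had a neighbour in the cell itself and 8.86% (cell 4) to 10.6% (cell 6) a neighbour in another cell. Neighbours here could share a fragment end, which can raise the share within a cell. Against ensemble draws in place of the cell, sharing with other cells was lower in cells 1 and 4 (-0.661 and -0.666 points) and higher in the other 8 cells, up to 1.26 points in cell 7. All 10 cells passed the two-sided permutation test by draws, 8 above the ensemble and 2 below, with a highest adjusted p of 0.00799 (cell 9). The mean difference of 0.613 points ± 0.749 (SD, n = 9) was 0.316 at a radius of 500 kb and 0.360 in thinned cells, with 8 of 9 Bgl II cells past the threshold in each.

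Bin pairs of the pool and the ensemble had correlated values. Across pairs of 10 Mb bins on different chromosomes, the counts correlated with Pearson r = 0.803 and Spearman rho = 0.758. These trans counts were not divided by the contact totals of their bins. Bins rich or poor in contacts in each map can thus give such a correlation without a shared pattern of trans contacts. How much of it they give was not tested. Across pairs of 1 Mb bins on 1 chromosome, contacts over the mean of their distance correlated with r = 0.507 and rho = 0.527. A part of the ensemble of the pool's size gave 0.972, 0.961, 0.762 and 0.702 against the whole, which is an upper reference because that part lies within it. Bin pairs are not independent replicates, so no p is given.

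Cell 8, cut with Dpn II, lay within the range of the 9 Bgl II cells for 20 of 22 quantities. The exceptions were autosomal ends with more than 1 partner (0.230% against 1.17% to 1.90%) and the within-domain share (66.3% against 66.5% to 71.5%). With 1 Dpn II cell, enzyme and cell cannot be told apart.

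Regions with few contacts were sought in 5034 regions of 500 kb. Contact ends per fragment end in the ensemble were lowest on chromosome 14 from 54000001 to 54500000, at 0.0937 of the chromosome's median, with 445 contact ends on 76 fragment ends. The value was 0.249 in the pool and 0.483 in the 10 cells, with 63 and 10 contact ends. The next 4 were on chromosome 11, starting at 13500001, 14500001, 15500001 and 15000001 (0.363, 0.371, 0.379 and 0.385), where the pool was at 0.820 to 0.900. Windows of 100 kb with at least 30 fragment ends were chosen after these values were seen. On chromosome 14 those from 54400001 to 54800000 were under 0.2 of the median in the ensemble. The next window, from 54800001 to 54900000, was at 1.94. No window between 53300000 and 54400001 had enough fragment ends, so where the low stretch begins on the left is not known.

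**Figure D5:**
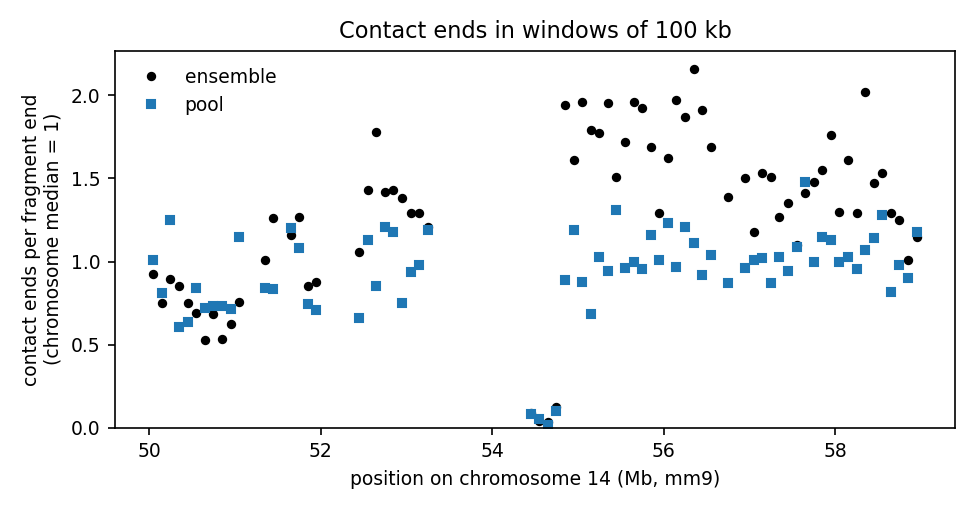
Contact ends per fragment end relative to the chromosome's median (vertical axis) in windows of 100 kb on chromosome 14 (Mb, mm9, horizontal axis) with at least 30 fragment ends, in the ensemble (black) and the pool (blue). The 4 windows between 54400001 and 54800000 lie at or under 0.124, and no window between 53300000 and 54400001 had enough fragment ends to be drawn.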

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

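Every test of an explanation in this part was chosen after the result it bears on was seen. The 2 tests of contacts between flanks also concern regions already seen to be low, and only their bounds were written before the flank values were seen. Of 43 sets of values over the 9 Bgl II cells, 2 had a cell far from the others, where chance gives about 1 in 20. Cell 4 had the lowest within-domain share, 66.5%, and the largest difference in trans share between class 1 and class 2, 8.61 points. Its shifted boundaries gave 59.9%, the lowest too, and its excess over them, 6.55 points, lay within the range of the other cells.

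Trans share differed widely between cells, and random ligation as the whole cause would add trans contacts with no neighbour. At equal depth the number of trans contacts with a neighbour instead rose with trans share over the 9 Bgl II cells (Spearman rho = 0.767, exact permutation p = 0.0214, adjusted over 3 relations 0.0433; Pearson r = 0.854, exact permutation p = 0.00558, adjusted 0.0167). Without the 2 cells farthest from the median r was 0.892 (exact permutation p = 0.00952) and rho 0.714 (exact permutation p = 0.0881). This number is a part of all trans contacts, so the 2 values are not independent. The share with a neighbour did not rise from the lowest to the highest trans share, with 139 of 776 trans contacts in cell 1 and 345 of 2932 in cell 2. Between them in trans share, cell 9 had 100 of 1744. Random ligation may still supply a part, as the trans excess within classes fell with trans share (rho = -0.7, exact permutation p = 0.0433, adjusted 0.0433; r = -0.652, exact permutation p = 0.0555, adjusted 0.0555). Without the 2 cells farthest from the median r was -0.774 (exact permutation p = 0.0369) and rho -0.821 (exact permutation p = 0.0341). Contact number stays open: between neighbours in contact number trans share differed by a median of 3.09 points against 7.40 over all 36 pairs (exact permutation p = 0.00767) and by a mean of 5.24 against 8.04 (exact permutation p = 0.0362), yet cells 1 and 2, also neighbours, differed by 18.9. This comparison, its statistics and bounds chosen with the differences in view, replaced that of cells 1 and 2 alone. The labels name no group of cells that differs in biology beyond the enzyme, so no biological cause was tested, and the state of each cell stays open.

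The ensemble held far more trans contacts than the pool. Listing each distinct contact once would thin out near cis contacts, but among trans contacts and cis contacts over 1 Mb, where 0.0866% of possible end pairs at 1 to 10 Mb were seen, the ensemble's trans share was still 27.9 points above the pool's (60.6% against 32.7%). Random ligation in the ensemble library is a candidate explanation: the trans excess within classes was 0.335 of the pool's. A mixture with random pairs that gives the ensemble's trans share would leave 0.236, if random pairs had no excess over shifted tracks. For this, 41.0% of the ensemble's contacts would have to be random. By the ensemble's own class shares, however, random pairing would put 31.5% of trans contacts within class 1 and 19.2% within class 2. Together these lie under the 52.5% of shifted tracks, so such a mixture would leave less than 0.236, farther from the 0.335 observed. Different filters on read pairs, or different cells, stay open, since neither was tested.

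On chromosome 14, 4 of 22621 autosomal windows of 100 kb had under 0.2 of their chromosome's contact ends per fragment end in the ensemble, all adjacent, from 54400001 to 54800000 (median 0.0655), and attention was drawn there partly by the known loss of DNA at antigen receptor genes in T cells. In these 4 windows, which held at least 30 ensemble fragment ends each, a lack of fragment ends is argued against by the pool. The windows were picked by their ensemble values, and the pool had a median of 0.0693 there. The pool is not an untouched check, because its values from 54000001 to 54500000 (0.249) and from 54500001 to 55000000 (0.519) had been seen. The latter also helped to set the interval from 54000001 to 55000000. Windows with fewer fragment ends were left out, so such a lack stays open to the left of 54400001. The pool measure replaced the number of fragment ends from 54000001 to 55000000, at the 7.11th percentile of the chromosome, which decided nothing. Loss of this DNA in many cells may explain the pattern. Contacts between the flanks of 54000001 to 55000000 could not test it, because the 300 kb to the left of that interval held 0.0145 of the usual contact ends. A mapping difference stays open, and so does a strain difference, although the labels give C57BL/6 mice. A ranking by the pool, with its minimum of 150 fragment ends, was chosen after the first list of regions was seen. Chromosome 6 from 41000001 to 41500000 was the lowest there (0.498), and the next regions were at 0.519, 0.607, 0.615 and 0.618. In the ensemble it was at 0.566, above a region of that list on chromosome 13 from 87000001 (0.487). The 228 contacts between the flanks of the chromosome 6 region were 2.65 times the median, the direction a loss gives. They lay at the 88.4th percentile of 22557 positions (83.9 to 92.2 at the 95% Poisson bounds), under the bound of 95 set beforehand. The prediction for a loss of this interval was thus not met. The flanks were fixed and the power of the test was not checked, so a loss of part of the interval, or in few cells, stays open. A lack of fragment ends stays open there, with 0.45 in the pool at the window lowest in the ensemble (0.311) and a number of fragment ends at the 5.12th percentile.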

How the results depend on the processing

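The setting with neighbours at least 20 kb away, and the interval used for correlations of bin pairs, were chosen after the data were seen. Of 217 recomputed values, 117 left out 1 of the 9 Bgl II cells in turn. That cannot move a mean over 9 cells by 1 SD, so these values, of which 0 moved, tell nothing of stability. In all, 200 moved by less than the spread between cells or kept the count of cells past the threshold within 1.5 times. Another 17, all under other settings, moved further, and 0 changed direction. The cause was not tested unless named. The slope fitted from 500 kb to 50 Mb was -0.649. X per ensemble fragment end was 0.423, and in thinned cells 0 of 9 passed on X, where each cell has fewer contacts. The within-domain excess was 7.76 points at 25 kb bins, 6.22 with a 250 kb window, 4.89 at 20 kb to 2 Mb and 9.46 at 200 kb to 1 Mb, with 9 of 9 Bgl II cells past the threshold. Without balancing, the trans excess within classes was 1.00 points and 1 cell passed; there 128 of 190 chromosome pairs had opposite signs in ensemble trans contacts. Pool and ensemble correlated with 0.703, 0.585 (trans, Pearson and Spearman), 0.340 and 0.371 (cis) at smaller bins, where counts per bin are lower, and with 0.798, 0.753, 0.499 and 0.520 without the 9 Bgl II cells, each outside an interval that takes bin pairs as independent. Thinning lowered the mean dispersion over chromosome pairs to 9.51 and the trans clustering excess to 12.6 points, inside a wide spread between cells. Requiring neighbours at least 20 kb away at both ends left 9 of 9 Bgl II cells past the threshold. Contacts with at least 2 reads and the gene groups were not run, for want of read numbers and of an mm9 annotation used here. No paired analysis was possible because the groups share fewer than 2 numbers. Contacts per cell limit single regions: the named domains rest on 103 to 198 contact ends.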

Other observations

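The counts of domains and the relation tested in this part were chosen after the values were seen. Of the 100 domains with the highest trans share in the 10 cells summed, 79 were of class 1, and of the 100 with the lowest, 19 were. The ensemble drew 55.4% of its contact ends from class 1, the pool 43.8% and cell 8 48.05%, and the 9 Bgl II cells 40.7% (cell 9) to 46.2% (cell 10). Chromosome X took 1.34 ± 0.0901 (SD, n = 9) times its ensemble share of contact ends in the Bgl II cells, chromosome 3 1.17 ± 0.0741 and chromosome 11 0.822 ± 0.0265.

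The share of cis contacts over 50 Mb rose with trans share over the 9 Bgl II cells (Spearman rho = 0.717, exact permutation p = 0.0369, adjusted over 3 relations 0.0433; Pearson r = 0.722, exact permutation p = 0.0300, adjusted 0.0451). Cells 1, 6 and 10 were low in distant cis contacts (4.15%, 7.15% and 5.18%), and cells 2 and 4 high (12.7% and 15.4%). Cell 7 went the other way, with 11.4% at a trans share of 14.2%, and cell 10 had a trans share of 18.3%, near the mean. Cells may differ in how far their chromosomes spread, a hypothesis with rho 0.717 behind it. Without the 2 cells farthest from the median trans share, r was 0.50 (exact permutation p = 0.263). Over the 7 cells left the relation was thus not shown, and whether it depends on those 2 cells stays open.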
